A study of Mus musculus with 12 samples.

How the data were processed

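RNA and antibody tags of 4 TEA-seq libraries from wild-type mouse bone marrow were analysed, 2 of sorted HSC-MPP cells and 2 of sorted MultiLin cells. Groups and replicate numbers were taken from the sample titles. Per the labels, cells were stained with a titrated panel of 112 antibodies and captured with a 10x Chromium 3' kit. The authors' processing notes name Cell Ranger (no version given), Seurat 4 and the mouse genome mm10. The deposited matrices hold raw UMI counts per gene or antibody tag and cell barcode, all whole numbers, for 28692 genes and 112 antibodies, and no normalization by the authors was found in them. The barcodes had already been selected by the authors, by a rule the labels do not give: 12588 and 11891 in HSC-MPP and 21669 and 22305 in MultiLin. Samples listed apart for antibody tags and for chromatin accessibility were not analysed here, since the RNA matrices held the antibody counts.

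Cells were kept with at least 500 genes detected and at most 20% of UMIs from mitochondrial genes, after doublets were removed per library with Scrublet (run through scanpy 1.11.5, automatic thresholds, which called 10.8, 11.4, 6.80 and 17.9% of barcodes). Kept cells held 63046332, 58212068, 11582989 and 18239768 RNA UMIs and 28048300, 20411689, 5396316 and 7507271 antibody counts in HSC-MPP replicates 1 and 2 and MultiLin replicates 1 and 2. At these depths a count of 3 UMIs, used as the floor, amounted to well under 1 CPM in each library. Exact 95% binomial intervals were computed for shares of cells, and intervals and floors cover counting error only. The spread between replicates was set against Poisson counting error as a chi-square per degree of freedom, which was 4.70 for HSC-MPP and 9.64 for MultiLin. No correction for free RNA was made.

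Kept cells of all libraries were log-normalised and clustered once with scanpy (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1 with leidenalg 0.10.2 and igraph 0.11.9, no batch integration). A cluster got the class of the cell type list with most raised markers, at least 3, where a marker was raised if at least 5% of the cells held it and its CPM was at least 2 times that of the other cells of the population that held most of the cluster. A cluster whose 10 genes of highest fold held more markers of another list, or with few UMIs and no own marker among them, stayed unnamed. This naming rule was set after the clusters and class counts had been seen and was changed once, before any test within a class: its first form asked for 3 UMIs of a marker and compared with the cells of all 4 libraries.

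Counts were summed per library over kept cells, since cells are not replicates. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, MultiLin over HSC-MPP, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and against a change of 2-fold with glmTreat, an addition made after the data were seen. Every adjusted p of a gene or tag comes from this model unless another tool is named, and every p is two-sided. CPM were computed by edgeR from TMM-scaled library sizes, and values are means ± SD over 2 libraries. TMM factors were 1.36, 1.34, 0.717 and 0.764, the biological coefficient of variation was 0.0326 for whole libraries and 0.150 for tags, and 2 residual degrees of freedom were left. The same test was run within each class with at least 50 cells in every library, which were the granulocyte-monocyte-like, megakaryocyte-like and erythroid-like classes. Antibody counts were tested likewise without the filter on low counts.

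The 31 gene lists were fixed before the data were examined, as were the comparisons, tests, cell filters and the rule for named genes. Of these, 13 are cell type lists: HSC, lymphoid-primed, granulocyte-monocyte, monocyte-dendritic, mature neutrophil, megakaryocyte, erythroid, basophil-mast-eosinophil, B cell, T and NK cell, plasmacytoid dendritic, macrophage, and stroma and endothelium. The other 18 are gate markers, MHC class II, HoxA and HoxB cluster and cofactors, G1/S, G2/M, cell cycle inhibitors and quiescence, ribosome biogenesis and MYC targets, interferon response, immediate early and dissociation stress, glycolysis, nuclear oxidative phosphorylation, mitochondrial transcripts, neutrophil granule and lysosome enzymes, erythro-megakaryocytic, myeloid and lymphoid transcription factors, cytokine receptors, and the Gimap family. Lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01 and, as alternatives, an estimated correlation and fry, with Benjamini-Hochberg adjustment over all lists. Camera compares the genes of a list with all other genes. Genes were also adjusted over the list alone.

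Genes were named by rule: the 10 with the largest change in each direction among those that passed, with a mean of at least 20 CPM over the 4 libraries and no overlap between the populations' libraries, up to 4 members of each list with the smallest adjusted p, all gate markers, and 5 genes per direction within a class. A gene and a tag that the rules for names select were not used here. Tags were named by the same rule without the CPM limit, a choice that the fixed rule does not cover and that was made after the data were seen. Where a group was at 0 UMIs, the fold is a bound against the floor of 3 UMIs per library. Coordinates and gene types are from GENCODE vM21 on mm10, which held 28339 (98.8%) of the gene identifiers.

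For transcripts of more than one lineage, each cell was thinned at random, with a fixed seed, to 1000 UMIs, shallower cells were left out (104, 105, 47 and 54), and the share of cells with at least 1 UMI of both kinds of list was set against the product of the single shares. The smallest two-sided exact permutation p for 2 libraries against 2 is 0.33, so shares were not tested.

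Alternatives covered DESeq2 1.42.0, RLE factors, no filter on low counts, at least 200 or 1000 genes per cell, at most 5% mitochondrial UMIs, doublets kept, cells thinned to 1000 UMIs, equal cell numbers, replicate number as a block, each library left out in turn, Leiden resolutions 0.5 and 1.5, thinning to 2000 UMIs, at least 2 UMIs per list and scaling of tags to total antibody counts. With a library left out, the lone library of its population was assumed to vary like the other pair. Chosen after the data were seen were no mitochondrial limit, kept cells with 10 to 20% mitochondrial UMIs alone, removal of mitochondrial and ribosomal RNA repeat features, the shared granulocyte-monocyte-like cluster alone, naming against all 4 libraries, scaling of tags to isotype controls, cells not thinned, and leaving out libraries for the shares.

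The tests were also run on simulated data with the observed mean CPM, library sizes and fitted common dispersion, in which 200 genes (20 tags) were changed. Changes of 1.5-fold, 2-fold and 4-fold were recovered for 74.6, 83.6 and 93.8% of genes in whole libraries, with 5 false calls among 14862 unchanged genes. Within classes a 2-fold change was recovered for 79.7, 74.2 and 79.1% of genes (granulocyte-monocyte-like, megakaryocyte-like and erythroid-like), with 8, 7 and 3 false calls. A list of 20 simulated genes was called, and 0 of 31 unchanged lists were. Simulated genes were drawn independently of each other, so this does not test list calls under correlation between genes. Far more genes changed in the data than in the simulation, which limits what its false calls tell. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.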

Results

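RNA and surface antibody tags were counted in the same single cells of wild-type mouse bone marrow by TEA-seq, a droplet assay that also reads open chromatin. Per the labels, 2 populations were sorted and each was captured in 2 libraries. HSC-MPP cells lacked lineage markers and carried Sca1 and CD117, and the CD48+ CD150- cells were left out, which gives a gate for haematopoietic stem cells (HSC) and multipotent progenitors. MultiLin cells lacked lineage markers, carried CD117 and CD34, were positive or low for CD16/32, and lacked CD115, CD11b, Ly6C and CD150. Total RNA UMIs were 74946303 and 69577985 in HSC-MPP replicates 1 and 2, and 51650387 and 73683167 in MultiLin replicates 1 and 2. Total antibody counts were 33582612 and 24571456 in HSC-MPP, and 21707624 and 27709206 in MultiLin.

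RNA quality differed between the populations. Mitochondrial transcripts held a median of 5.14 and 5.51% of the UMIs of an HSC-MPP barcode, and of 22.5% in both MultiLin libraries. The limit of 20% mitochondrial UMIs was exceeded by 59.8 and 61.1% of MultiLin barcodes, against 0.683 and 0.748% of HSC-MPP barcodes, so most MultiLin barcodes were left out. Kept cells numbered 11077 and 10389 in HSC-MPP (88.0 and 87.4% of barcodes), and 6227 and 7400 in MultiLin (28.7 and 33.2%). Kept HSC-MPP cells had medians of 4898 and 4854 UMIs and of 2446 and 2421 genes, and kept MultiLin cells of 1646 and 2176 UMIs and of 768 and 1018 genes. Among kept cells the median mitochondrial share was 5.12 and 5.49% in HSC-MPP and 14.4 and 14.7% in MultiLin. Features of the ribosomal RNA repeat (Gm42418, AY036118 and Gm26917) held medians of 1.71 and 1.64% in HSC-MPP and of 24.8 and 21.3% in MultiLin. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these libraries.

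The series title names the definition of multipotent progenitor hierarchies as its purpose, and the whole-library comparison asked which transcripts separated the gates. Summed over kept cells, MultiLin libraries held far more RNA of granule proteins of neutrophils, basophils and eosinophils, and far less RNA of stem cell regulators. Mpo, which encodes myeloperoxidase (ENSMUSG00000009350, chromosome 11, positions 87793581 to 87804413, mm10), rose from 148 ± 16.2 to 5951 ± 176 CPM (SD, n = 2 libraries each), a log2 change of 5.33 (SE 0.07, adjusted p = 3.6e-16). Ly6a, which encodes the Sca1 antigen of the HSC-MPP gate (ENSMUSG00000075602, chromosome 15, positions 74994877 to 74998031), fell from 56.3 ± 2.49 to 4.36 ± 0.480 CPM, a log2 change of -3.72 (SE 0.10, adjusted p = 1.1e-13). Of 15327 genes tested, 5825 were higher and 5919 lower in MultiLin. Tested against a change of 2-fold, 1566 were higher and 1970 lower, 3536 in all, and 115 and 185 among cells with 10 to 20% mitochondrial UMIs.

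The 10 largest rises were in Ltf (lactoferrin, log2 6.77), Epx (eosinophil peroxidase, 6.10), Prss34 and Mcpt8 (basophil proteases, 5.73 and 5.65), Prg2 (eosinophil major basic protein, 5.72), C3 (complement component, 5.36), Mpo, Lcn2 (lipocalin-2, 5.24), Clec12a (a lectin receptor of myeloid cells, 5.17) and Chil3 (a chitinase-like protein of myeloid cells, 5.14). Ltf (chromosome 9, positions 111019271 to 111042767) went from 2.16 ± 0.742 to 235 ± 29.1 CPM, and Clec12a from 8.26 ± 0.543 to 298 ± 3.71 CPM. Several of these rises were in genes that marked small clusters. Ltf, Lcn2 and Chil3 were among the 10 genes of highest fold in the mature neutrophil-like cluster (110 and 129 MultiLin cells). Epx and Prg2 were so in a cluster of 63 and 76 MultiLin cells, and Prss34 and Mcpt8 in one of 457 and 677. Such rises are not a measure of the typical MultiLin cell. Epx rested on 97 and 1 UMIs in the HSC-MPP libraries, and without HSC-MPP replicate 1 its fitted change was 11.27. Prg2 stood at 10.1 and 1.51 CPM in the HSC-MPP libraries, and without replicates 1 and 2 of HSC-MPP its change was 7.69 and 4.95, and that of Chil3 4.54 and 6.02. The largest falls outside the immunoglobulins were in Sema3d (a secreted semaphorin, -5.19, from 59.1 ± 1.22 to 1.66 ± 0.212 CPM; chromosome 5, positions 12383385 to 12588948), Il1rapl2 (of the interleukin-1 receptor family, -4.99), Myof (myoferlin, -4.37), Gm16070 (annotated as antisense, -4.16), Abcg3 (an ABC transporter, 59.9 to 3.54 CPM), Tnip3 (a regulator of NF-kappaB signalling, -3.89), Ly6a and Prex2 (an exchange factor for Rac, -3.63). The strand behind the counts was not checked, which limits what the values of antisense genes can be tied to. The immunoglobulin constant region genes Igkc (chromosome 6, positions 70726435 to 70726966) and Ighm fell too. Igkc went from 311 ± 99.4 CPM to 0 UMIs in both MultiLin libraries, at least 1079-fold lower against a floor of 3 UMIs per library, and Ighm from 240 ± 26.6 to 6.70 ± 0.236 CPM. Of the HSC-MPP UMIs of Igkc, 86.9 and 88.8% lay in 10 and 9 B cell-like cells, as did 81.1 and 85.9% of those of Ighm.

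The genes of the fixed gate marker list, which also holds Flt3 and Il7r although these gates do not use their products, moved in both directions. Fcgr3 and Fcgr2b, which encode the CD16 and CD32 Fc receptors, rose by log2 4.99 and 3.85. Ly6c2 (Ly6C, 4.77), Csf1r (CD115, 3.39) and Itgam (CD11b, 2.70) also rose, from 7.55, 1.45 and 2.19 to 204, 15 and 14.5 CPM, although the MultiLin gate excluded the 3 antigens. Cd48 rose by 1.22, Cd34 by 0.52 (133 to 190 CPM) and Kit (CD117) by 0.46 (467 to 643 CPM). Flt3, a receptor of early lymphoid progenitors, fell by log2 2.74 (244 to 36.5 CPM), Slamf1 (CD150) by 0.52 (29.8 to 21.2 CPM) and Ly6c1 by 1.75 (0.610 to 0.144 CPM, adjusted p = 0.0232). Ly6c1 held 0 and 4 UMIs in MultiLin, and its fitted change was -1.08 (adjusted p = 0.129) without MultiLin replicate 1, whereas without MultiLin replicate 2 the fall is only bounded, at 1.69-fold or more against 3 UMIs. Il7r did not pass (0.41, adjusted p = 0.266), and stood at 0.85 (adjusted p = 0.0157) and -0.81 without MultiLin replicates 1 and 2. Of the 13 gate marker genes, 8 rose and 4 fell (median 0.52), and the list as a whole did not pass (adjusted p = 0.127), with a median of 1.05 without MultiLin replicate 1. At most 5% mitochondrial UMIs, Cd34 and Kit stood at -0.20 and -0.79, but 1431 of 1509 and 1030 of 1141 MultiLin cells in that setting lay in 1 unnamed cluster, with median ribosomal RNA repeat shares of 44.6 and 40.7%. Among cells with 10 to 20% mitochondrial UMIs, Slamf1 stood at 0.087 (adjusted p = 0.765), and Ly6c2 (0.23), Csf1r (0.26) and Itgam (0.77) did not pass. Ly6c1 did not pass with DESeq2 (adjusted p = 0.0812). In that same window, chosen after the data were seen, 4521 genes passed in all, and 318 of the 4245 genes called in both settings had the opposite direction. With at most 5% mitochondrial UMIs, 4390 genes were higher and 5267 lower, and 361 of the 8799 called in both settings had the opposite direction.

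Genes of stem cells were lower in MultiLin. All 10 members of the HSC list fell (median log2 -2.20, adjusted p = 0.000477, and adjusted p = 0.474 with an estimated correlation), among them the transcription factors Mecom (-2.79, 2028 to 293 CPM) and Hlf (-3.07, 822 to 97.3 CPM), the exchange factor gene Fgd5 (-3.53) and the transcriptional cofactor Mllt3 (-1.43). All 10 genes of the HoxA and HoxB clusters and their cofactors fell as well (median -1.61, adjusted p = 0.000700, and adjusted p = 0.474 with an estimated correlation). Meis1, a partner of Hox proteins, fell by 1.34 (1745 to 690 CPM), Hoxa9 by 1.81, Hoxa7 by 1.13 and Hoxb3 by 1.91. Of 8 Gimap genes, GTPases best known from lymphocytes, 7 fell (median -3.07, adjusted p = 0.000851, and adjusted p = 0.474 with an estimated correlation), with Gimap6 at -3.24 (162 to 17.1 CPM), Gimap1 at -1.61 and Gimap5 at -2.43. Of 18 interferon response genes, 16 fell and Bst2 rose by 0.83 (median -0.83, adjusted p = 0.000666, and adjusted p = 0.474 with an estimated correlation). Ifitm1 (-2.02, 131 to 32.8 CPM), Ifitm3 (-1.85) and Oas2 (-2.62), which act against viruses, were among those that fell. Of 17 immediate early and dissociation stress genes, 13 fell and 3 rose (median -0.64, adjusted p = 0.0218, and adjusted p = 0.474 with an estimated correlation). Fos (-1.35, 98.7 to 38.8 CPM), Egr1 (-1.27) and Klf6 (-1.43), transcription factors of the early response, fell, whereas the heat shock gene Hspa1b rose from 4.51 to 25.2 CPM, as did Hspa1a and Jund, which are named here because their values were seen. For the immediate early list the call ended without MultiLin replicate 2 (median -0.73, adjusted p = 0.0844), and its median was 0.21 (adjusted p = 0.207) among cells with 10 to 20% mitochondrial UMIs. Adjusted over the list alone, the counts of each of the 31 lists were the same as over all genes tested, except for nuclear oxidative phosphorylation genes, 14 instead of 13. All 20 lists that passed with the preset correlation lost the call with an estimated correlation. That correlation was estimated from 2 residual degrees of freedom. Many unlike lists then shared the smallest adjusted p, 0.474, so this setting cannot tell lists that shifted from those that did not. The list calls therefore rest on the preset correlation.

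Lymphoid and plasmacytoid genes were lower as well, in part. Of 9 lymphoid-primed genes tested, 6 fell and 1 rose (median -1.02), and the list did not pass (adjusted p = 0.0604), although it did without HSC-MPP replicate 2 (adjusted p = 0.0448), without MultiLin replicate 2 (0.0445), with at least 1000 genes per cell (0.0483) and with no mitochondrial limit (0.0334). Flt3, Mef2c (-1.02), the leukocyte-specific Lsp1 (-1.47) and Dntt, which encodes terminal transferase (10.1 to 0.781 CPM), were its members with the smallest adjusted p, and Notch1 was the member that rose (0.47). Of 7 plasmacytoid dendritic genes, 6 fell and Bst2 rose (median -1.37, adjusted p = 0.0218, and adjusted p = 0.523 with an estimated correlation), with Runx2 at -1.15, the chemokine receptor gene Ccr9 at -3.08 and the transcription factor gene Tcf4 at -0.55. The plasmacytoid call ended without MultiLin replicate 1 (adjusted p = 0.0533), among cells with 10 to 20% mitochondrial UMIs (adjusted p = 0.19), with at least 1000 genes per cell (0.0737) and with no mitochondrial limit (0.0673). Of 12 lymphoid transcription factors, Tcf3 (0.88), Sox4 (0.61) and Notch1 were among 4 that rose, Tcf4 among 5 that fell, and the list did not pass (median 0.00, adjusted p = 0.980). B cell genes did not pass as a list (6 tested, 1 higher, 3 lower, median -0.98, adjusted p = 0.797). Nor did T and NK cell genes, of which 2 were tested, Nkg7 higher (1.89) and Ccl5 lower (-2.34; median -0.23, adjusted p = 0.621, with a set test that pointed up). B cell gene Bank1 fell by 3.64 (32.5 to 2.47 CPM) and Cd79b rose by 0.55. Medians of these short lists depended on single libraries. That of the B cell genes was -2.39 and -2.29 without HSC-MPP replicates 1 and 2 and -1.67 without MultiLin replicate 1. For the T and NK genes it was -0.11 without HSC-MPP replicate 1 and 0.33 and -2.56 without MultiLin replicates 1 and 2. With a library left out, the lymphoid transcription factors had medians between -0.20 and 0.03.

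Myeloid genes were higher in MultiLin. Of 10 granulocyte-monocyte genes, 9 rose and Csf3r, the G-CSF receptor gene, fell by 0.29 (median 4.23, adjusted p = 0.000700, and adjusted p = 0.523 with an estimated correlation). Clec12a, Mpo, Ms4a3 (4.78, 6.60 to 181 CPM) and the protease gene Prtn3 (4.17, 79.5 to 1433 CPM) had the smallest adjusted p. All 12 neutrophil granule and lysosome enzyme genes rose (median 1.78, adjusted p = 0.000143, and adjusted p = 0.474 with an estimated correlation), including Ctsg (cathepsin G, 4.16) and Cst7 (3.87), and 4 of the 12, Mpo, Elane, Prtn3 and Ctsg, are also in the granulocyte-monocyte list. All 10 mature neutrophil genes rose (median 5.06, adjusted p = 0.000289, and adjusted p = 0.523 with an estimated correlation), among them Camp (4.01, 8.34 to 134 CPM) and S100a8 (2.79). All 10 basophil, mast cell and eosinophil genes rose (median 5.47, adjusted p = 0.000289, and adjusted p = 0.474 with an estimated correlation), with the mast cell protease gene Cpa3 at 4.59 (23.5 to 565 CPM), the IgE receptor gene Ms4a2 at 4.95 and Il1rl1, which encodes the interleukin-33 receptor, at 3.72. Of 9 monocyte-dendritic genes, 7 rose and Klf4 fell (median 2.51, adjusted p = 0.0133, and adjusted p = 0.524 with an estimated correlation), with F13a1 at 3.65, the chemokine receptor gene Ccr2 at 5.03 and Irf8 at 2.76. Of 10 myeloid transcription factors, 8 rose and Klf4 fell (median 0.63, adjusted p = 0.0204, and adjusted p = 0.474 with an estimated correlation), with Cebpe at 5.61 (0.487 to 23.8 CPM), Cebpa at 4.12 (1.04 to 18.3 CPM) and Zeb2 at 1.10. Among cells with 10 to 20% mitochondrial UMIs the medians were 0.56 for the granulocyte-monocyte genes, 0.19 for the monocyte-dendritic genes (adjusted p = 0.461), 2.34 for the mature neutrophil genes (adjusted p = 0.0633) and 0.27 for the myeloid factors (adjusted p = 0.19), against -1.45 for the HSC genes. That window held 399 and 415 HSC-MPP cells and 4357 and 5722 MultiLin cells. Its HSC-MPP cells were 14.8 and 18.3% granulocyte-monocyte-like, 6.77 and 10.4% erythroid-like and 0.752 and 0.964% HSC-like, against 4.78 and 4.92%, 2.74 and 3.00%, and 10.7 and 9.88% of all kept HSC-MPP cells.

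Erythroid genes were higher in MultiLin, with exceptions, and megakaryocyte genes were mixed. Of 10 erythroid genes, 8 rose and 2, Car2 (-0.90, 297 to 159 CPM) and Hbb-bt, fell (median 1.53, adjusted p = 0.0276, and adjusted p = 0.552 with an estimated correlation). Ermap (2.74), the carbonic anhydrase gene Car1 (2.21, 30.3 to 140 CPM) and the erythroid transcription factor gene Klf1 (3.06) rose. Of 11 erythro-megakaryocytic transcription factors, 9 rose, including Gata2 (1.53, 66.4 to 192 CPM) and Myb (1.16), while Mef2c and Fli1 fell (median 1.16, adjusted p = 0.0113, and adjusted p = 0.474 with an estimated correlation). Of 9 megakaryocyte genes, 5 rose and 3 fell, and the list did not pass (median 0.49, adjusted p = 0.490), with a median of 0.24 without MultiLin replicate 2. Itga2b, the CD41 gene, rose by 2.14 (59.8 to 263 CPM), Gp5 by 2.35 and Pf4 by 0.82. The erythroid median was -0.46 (adjusted p = 0.214) among cells with 10 to 20% mitochondrial UMIs, and its call ended with no mitochondrial limit (adjusted p = 0.0521). Hbb-bt, Fli1, Csf3r and Klf4 are outside the rule for named genes and are named because their values were seen.

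Genes of growth and metabolism were mostly higher in MultiLin. All 16 ribosome biogenesis and MYC target genes rose (median 1.38, adjusted p = 1.6e-05, and adjusted p = 0.474 with an estimated correlation), among them Pa2g4 (1.61), Nop56 (1.44, 129 to 348 CPM), the nucleolar methyltransferase gene Fbl (1.70) and Dkc1 (1.33). Of 13 glycolysis genes, 11 rose and Slc2a1, a glucose transporter gene named because its value was seen, fell by 0.69 (median 1.22, adjusted p = 0.000997, and adjusted p = 0.474 with an estimated correlation). Ldha rose by 2.11 (50.4 to 218 CPM), Pgam1 by 2.36, Gpi1 by 1.76 and Gapdh by 1.24. Of 14 nuclear oxidative phosphorylation genes, 13 rose (median 0.78, adjusted p = 0.000477, and adjusted p = 0.523 with an estimated correlation), with Cox5a at 1.42, Atp5a1 at 1.19, Atp5b at 0.82 and Ndufb8 at 0.75. All 13 mitochondrial transcripts rose (median 2.17, adjusted p = 3.6e-05, and adjusted p = 0.474 with an estimated correlation), with mt-Nd5 at 2.28 and mt-Co1 at 2.26, beside the higher mitochondrial share of kept MultiLin cells (medians of 14.4 and 14.7%, against 5.12 and 5.49%). Of 20 G1/S genes, 17 rose (median 0.94, adjusted p = 0.000568, and adjusted p = 0.523 with an estimated correlation), led by the replication genes Mcm5 (1.64), Rrm2 (1.98), Mcm2 (1.56) and Mcm3 (1.33). Of 20 G2/M genes, 13 rose and 2 fell (median 0.32, adjusted p = 0.00546, and adjusted p = 0.474 with an estimated correlation), with Mki67 at 1.22 (464 to 1083 CPM), Cenpe at 1.11 and Cenpf at 0.83. Among cells with 10 to 20% mitochondrial UMIs the G2/M median was -0.49 (adjusted p = 0.000327) and the oxidative phosphorylation median -0.12 (adjusted p = 0.452).

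The remaining lists did not pass. Of 12 cell cycle inhibitor and quiescence genes, 8 fell and 3 rose (median -0.59, adjusted p = 0.134), with Txnip at -0.88, Btg2 at -0.99 and Btg1 at -0.65. Of 16 cytokine receptor genes, 8 rose and 4 fell (median 0.44, adjusted p = 0.134), with the interferon gamma receptor gene Ifngr1 at 2.46 (70.6 to 390 CPM), Cxcr4 at 2.48 and Csf2rb at 1.86, and the list passed without MultiLin replicate 1 (median 0.66, adjusted p = 0.0403), with at least 1000 genes per cell (0.0489) and with no mitochondrial limit (0.0289). Of 7 MHC class II genes, 5 fell and 2 rose (median -0.89, adjusted p = 0.427), with H2-Eb1 at -1.39 and H2-DMb1 at 0.80. Of 10 macrophage genes, 5 fell and 2 rose (median -0.67, adjusted p = 0.268), with the complement genes C1qb at -1.24 and C1qc at -1.71 and with Adgre1 (F4/80) at 2.33. Of 9 stroma and endothelium genes, 3 rose and 3 fell (median -0.56, adjusted p = 0.980), with the endothelial sialomucin gene Emcn at -3.48 (54.1 to 4.75 CPM) and Pdgfrb at 2.34. Without MultiLin replicate 2 the medians of the MHC class II, macrophage and stroma lists were -1.38, -1.14 and -0.90.

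**Figure D1:**
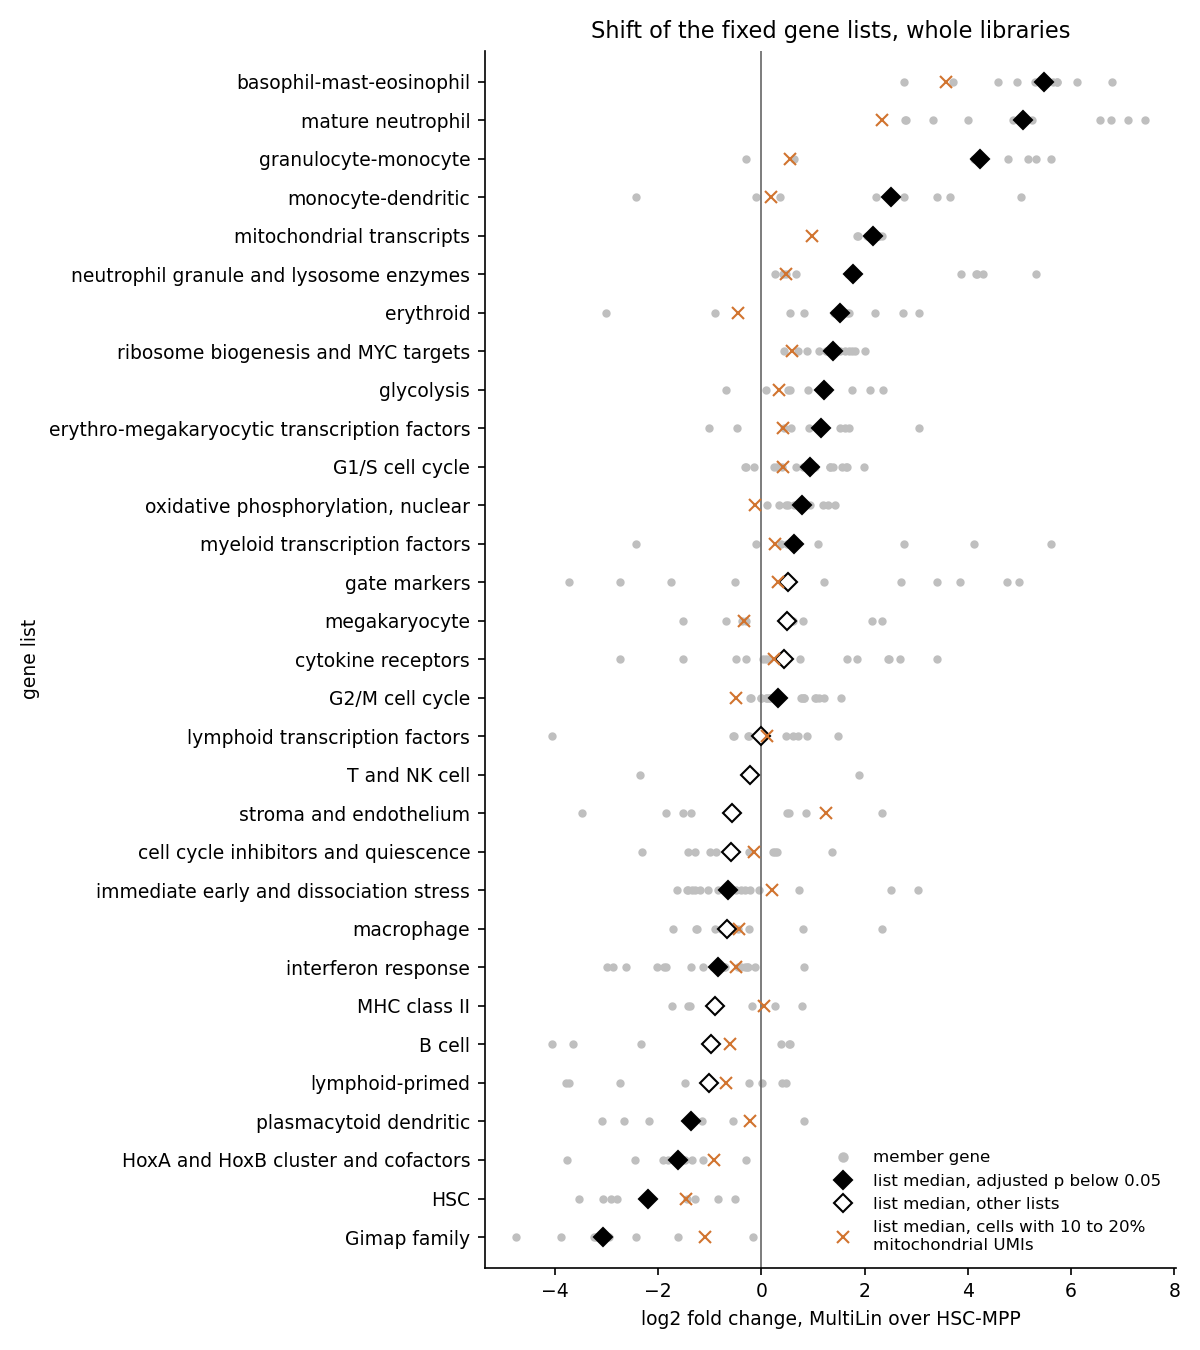
Log2 fold change, MultiLin over HSC-MPP, of the members of each of the 31 gene lists (grey dots), with the list median as a black diamond where the list passed and a white one where it did not, and the median among cells with 10 to 20% mitochondrial UMIs as an orange cross. Medians run from -3.07 for the Gimap genes to 5.47 for the basophil, mast cell and eosinophil genes, and the cross of the granulocyte-monocyte genes lies at 0.56, against a diamond at 4.23.

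Cell classes, given to clusters from fixed marker lists, were unevenly spread over the populations. HSC-like cells made up 10.7 and 9.88% of kept HSC-MPP cells (exact 95% intervals 10.1 to 11.3% and 9.31 to 10.5%), against 0 of 6227 and 1 of 7400 kept MultiLin cells. Lymphoid-primed-like cells made up 15.3 and 16.2% against 0 in both MultiLin libraries, where 3 cells would be 0.0482 and 0.0405%. Erythroid-like cells made up 2.74 and 3.00% of HSC-MPP and 21.1 and 22.5% of MultiLin cells. Basophil, mast cell and eosinophil-like cells made up 0.298 and 0.260% against 8.35 and 10.2%, and mature neutrophil-like cells 0.0903 and 0.0963% against 1.77 and 1.74%. Granulocyte-monocyte-like cells made up 4.78 and 4.92% of HSC-MPP and 6.38 and 10.4% of MultiLin cells, a mean difference of 3.56 points that was 5.60 and 1.53 points without MultiLin replicates 1 and 2. Megakaryocyte-like cells made up 13.4 and 13.3% against 8.69 and 10.9%, macrophage-like cells 1.87 and 1.41% against 0 and 0.0270%, and B cell-like cells 0.0903 and 0.0866% against 0. Clusters that met no class held 50.7 and 50.9% of HSC-MPP and 53.7 and 44.2% of MultiLin cells. The gates themselves select on CD150, CD34 and CD16/32, and kept HSC-MPP cells had more than 2 times the UMIs of kept MultiLin cells, so the classes were named at unequal depth. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.33, so no share was tested. Other settings turned the sign of the difference for megakaryocyte-like cells (-3.53 points, but 18.2 with at least 1000 genes per cell and 15.6 at resolution 0.5), erythroid-like cells (18.9, but -1.31 and -2.11 in these and -2.79 named against all 4 libraries), granulocyte-monocyte-like cells (3.56, but -0.623 with doublets kept) and HSC-like cells (-10.3, but 0.0680 at resolution 1.5). The near absence of HSC-like cells from MultiLin depended on the clusters, as their mean share there was 10.6% at resolution 1.5 and 13.7% with no mitochondrial limit (HSC-MPP 10.6 and 28.0%). Named against all 4 libraries, granulocyte-monocyte-like cells differed by 56.4 points. No cell was named lymphoid-primed-like with at least 1000 genes per cell, and none macrophage-like with no mitochondrial limit, at resolution 0.5 or with cells thinned. No kept cell was named monocyte-dendritic-like in the main clusters. With no mitochondrial limit such cells made up a mean of 9.39% of MultiLin and 0.149% of HSC-MPP cells.

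**Figure D2:**
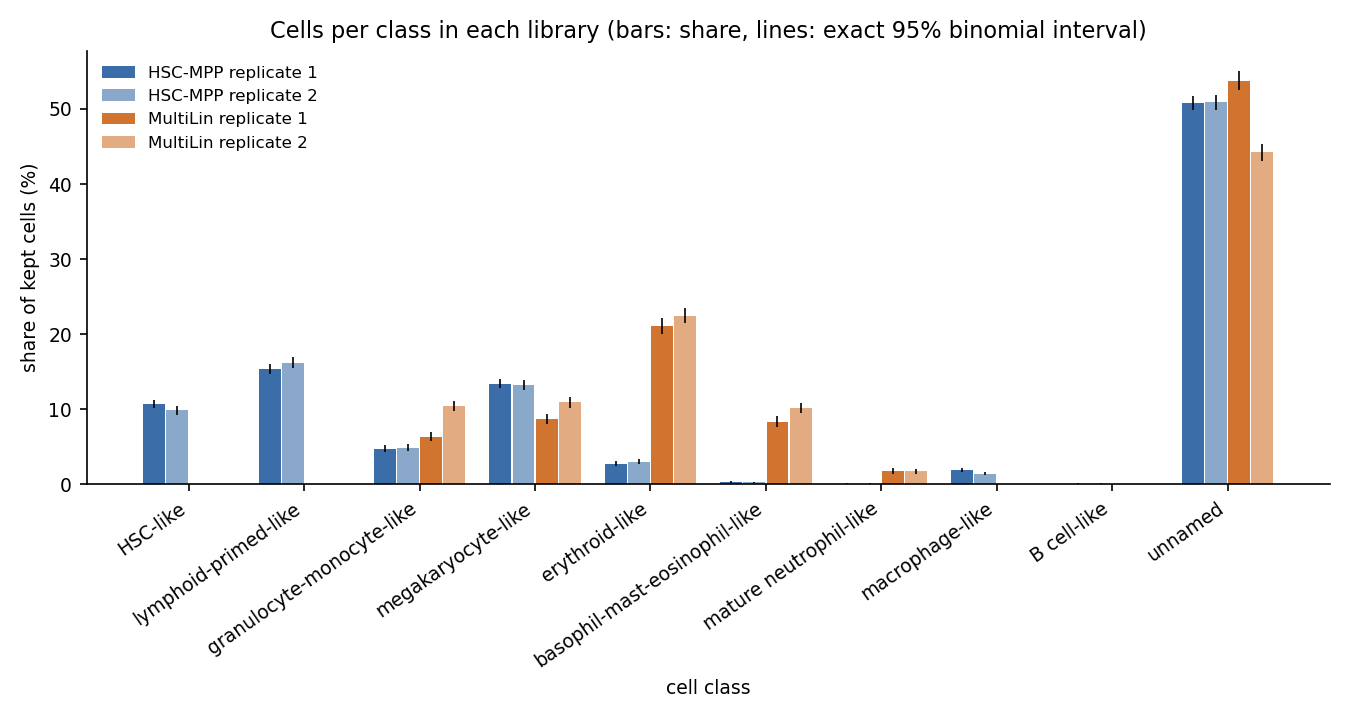
Share of kept cells in each class, in percent, for the 4 libraries, with bars for the shares and lines for exact 95% binomial intervals. Erythroid-like cells stand at 2.74 and 3.00% in HSC-MPP and at 21.1 and 22.5% in MultiLin, and HSC-like cells at 10.7 and 9.88% against 0 and 0.0135%.

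Within granulocyte-monocyte-like cells (529 and 511 HSC-MPP cells, 397 and 773 MultiLin cells), the comparison asked whether the gates differed where both held a class of the same name. Most HSC-MPP cells of the class (478 and 455) lay in a cluster without MultiLin cells. It had 3 raised granulocyte-monocyte markers, against 9 in the cluster of the MultiLin cells, and stayed unnamed when named against all 4 libraries. MultiLin cells of this class had more RNA of the granule proteins and less of stem cell regulators than HSC-MPP cells of the class. Mpo rose from 1676 ± 208 to 14336 ± 216 CPM (log2 3.10, SE 0.10) and Prtn3 from 493 to 3225 CPM (2.71), and 9 of 10 granulocyte-monocyte genes rose, all 10 adjusted over the list alone (median 2.63, adjusted p = 7.1e-05, and adjusted p = 0.370 with an estimated correlation). The granulocyte-monocyte list also named these clusters, each against its own population, so its p-value here is not independent of that naming. All 9 HSC genes tested fell (median -3.07, or -2.49 with genes at 0 UMIs set to their bound, adjusted p = 4.8e-05, and adjusted p = 0.326 with an estimated correlation), with Mecom at -4.50 (1599 to 74.0 CPM). All 7 basophil, mast cell and eosinophil genes tested rose (median 3.94, or 3.57 at the bound, adjusted p = 0.000265, and adjusted p = 0.326 with an estimated correlation). The largest rises were in Slc25a21 (a mitochondrial carrier, 6.11, 1.31 to 89.3 CPM), Prg2 (0.744 to 46.7 CPM), Cmss1 (4.01), Gm42418 (ribosomal RNA repeat, 3.97, 15508 to 242659 CPM) and Mcpt8 (3.94). Slc25a21 was among the 10 genes of highest fold in the erythroid-like MultiLin cluster. Prg2 and Mcpt8 were so in basophil, mast cell and eosinophil-like clusters. Free RNA from such cells was not tested as a source of these rises. The largest falls were in Eya2 (80.5 to 0.426 CPM), Cyp7b1 (-5.98), Col4a2 (collagen IV, -5.26), Prex2 (-5.13, or -6.58 and -3.80 without MultiLin replicates 1 and 2) and Palld (palladin, 114 to 3.31 CPM). Eya2 held 0 and 2 UMIs in MultiLin, and without MultiLin replicate 2 the fall is only bounded, at 25.1-fold or more against 3 UMIs. Median mitochondrial and ribosomal RNA repeat shares of the class were 6.28 and 6.56% and 2.04 and 1.93% in HSC-MPP, against 18.5 and 18.2% and 21.1 and 18.8% in MultiLin, and all 13 mitochondrial transcripts rose (median 2.17, adjusted p = 3.5e-07, and adjusted p = 0.326 with an estimated correlation). Of 11180 genes tested, 3449 were higher and 3368 lower, 866 and 918 of them by more than 2-fold. DESeq2 called 4409, cells thinned to 1000 UMIs 3063 (385 and 314 by more than 2-fold), and the clusters at resolution 0.5 gave 1492 (20 and 32). Without MultiLin replicate 2, 564 and 516 changed by more than 2-fold. The class joined clusters, and in the single cluster that held all its MultiLin cells but only 51 and 56 of its HSC-MPP cells, 1661 genes passed (20 higher and 33 lower by more than 2-fold), 108 of the 1477 called in both settings in the opposite direction.

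Within megakaryocyte-like cells (1485 and 1378 HSC-MPP cells, 541 and 808 MultiLin cells), the largest rises were in Mpo, Clec12a, Elane, Ctsg and Ly6c2. The cells compared lay in different clusters: a single cluster held all MultiLin cells of the class but 1, and only 5 and 4 of the HSC-MPP cells. Mpo went from 17.6 ± 3.06 to 2463 ± 26.4 CPM (log2 7.12, SE 0.08), Elane, the neutrophil elastase gene, from 3.29 to 337 CPM (6.68), Clec12a rose by 6.98, Ctsg by 6.44 and Ly6c2 from 0.994 to 109 CPM. Of 10 granulocyte-monocyte genes, 9 rose (median 5.83, adjusted p = 1.3e-07, and adjusted p = 0.294 with an estimated correlation). Megakaryocyte genes rose as well, 6 of 9 (median 0.68, adjusted p = 0.0118, and adjusted p = 0.332 with an estimated correlation), with Itga2b at 1.96 (241 to 937 CPM), Gp5 at 2.35 and the von Willebrand factor gene Vwf at 1.39. The megakaryocyte list also named these clusters, each against its own population, so its p-value is not independent of that naming. Of 9 HSC genes, 6 fell (median -1.09, adjusted p = 0.00190, and adjusted p = 0.294 with an estimated correlation), and of 20 G2/M genes 12 fell and 2 rose (median -0.57, adjusted p = 0.00778, and adjusted p = 0.388 with an estimated correlation), for example Tpx2 (-0.79). The largest falls were in Luzp2 (-3.06, or -4.20 without MultiLin replicate 2), P2ry12 (a purinergic receptor of platelets, -2.53), Agrp (-2.50) and the antisense genes Gm16599 (-2.70) and 1600010M07Rik (-2.47). Median mitochondrial and ribosomal RNA repeat shares were 6.10 and 6.50% and 1.76 and 1.70% in HSC-MPP, against 17.0 and 16.4% and 21.5 and 19.3% in MultiLin. Of 12014 genes tested, 2766 were higher and 2445 lower, 347 and 133 of them by more than 2-fold. Counts fell to 2685 without MultiLin replicate 2 (191 and 39 by more than 2-fold), 2709 with cells thinned to 1000 UMIs (191 and 43) and 3381 with DESeq2, and 626 and 563 changed by more than 2-fold at resolution 0.5.

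Within erythroid-like cells (303 and 312 HSC-MPP cells, 1312 and 1662 MultiLin cells), granulocyte-monocyte genes rose and erythroid genes fell. Here too the cells compared lay in different clusters: a single cluster held all MultiLin cells of the class, and only 2 and 15 of the HSC-MPP cells. Mpo went from 18.7 ± 1.88 to 2787 ± 19.6 CPM (log2 7.22, SE 0.10), Elane rose by 6.48, and all 10 granulocyte-monocyte genes rose (median 5.32, adjusted p = 2.1e-09, and adjusted p = 0.288 with an estimated correlation). Of 9 erythroid genes, 7 fell, or 8 adjusted over the list alone (median -0.97, adjusted p = 0.000370, and adjusted p = 0.288 with an estimated correlation), with Car1 at -1.41 (806 to 302 CPM), Car2 from 423 to 211 CPM, Ermap at -0.79 and Blvrb, a haem breakdown enzyme gene, at -1.16. The erythroid list also named these clusters, each against its own population, so its p-value is not independent of that naming. Raised erythroid markers numbered 7 in the largest HSC-MPP cluster of the class and 4 in the MultiLin cluster. HSC genes did not pass (median -0.11, adjusted p = 0.721). The basophil and eosinophil genes Prg2 (6.93) and Mcpt8 (6.73) were among the largest rises, with Clec12a at 7.36, which held no UMI in HSC-MPP replicate 2, so that without HSC-MPP replicate 1 the rise is only bounded, at 164-fold or more against 3 UMIs. Falls were largest in Igkc (56.4 CPM to 0 UMIs, at least 41.7-fold lower), Ighm (-3.55), Gm26577 (-3.28), Gm16599 (-2.89) and Gm26518 (-2.38). Ighm held only 10 and 7 UMIs in MultiLin cells of the class. In HSC-MPP, 10 and 9 B cell-like cells held 86.9 and 88.8% of the Igkc UMIs, and every other class held some. Free RNA from such cells was not tested as a source of the Igkc and Ighm falls. Median mitochondrial and ribosomal RNA repeat shares were 6.37 and 6.44% and 1.92% (both libraries) in HSC-MPP, against 15.1 and 14.8% and 24.1 and 21.2% in MultiLin. Of 10027 genes tested, 2263 were higher and 1964 lower, 279 and 93 of them by more than 2-fold. Counts fell to 2814 without MultiLin replicate 2 (229 and 32 by more than 2-fold), 1824 with DESeq2 and 1355 with cells thinned to 1000 UMIs (113 and 19). In MultiLin cells of the megakaryocyte-like and erythroid-like classes, the levels of 6 granulocyte-monocyte genes (Mpo, Elane, Prtn3, Ctsg, Ms4a3 and Clec12a) had a median of 0.246 to 0.318 of the level in the barcodes left out by the mitochondrial limit, and those of 4 basophil genes 0.473 to 0.661 (as CPM without TMM). For 4 mature neutrophil genes the medians were 0.590 to 0.938.

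**Figure D3:**
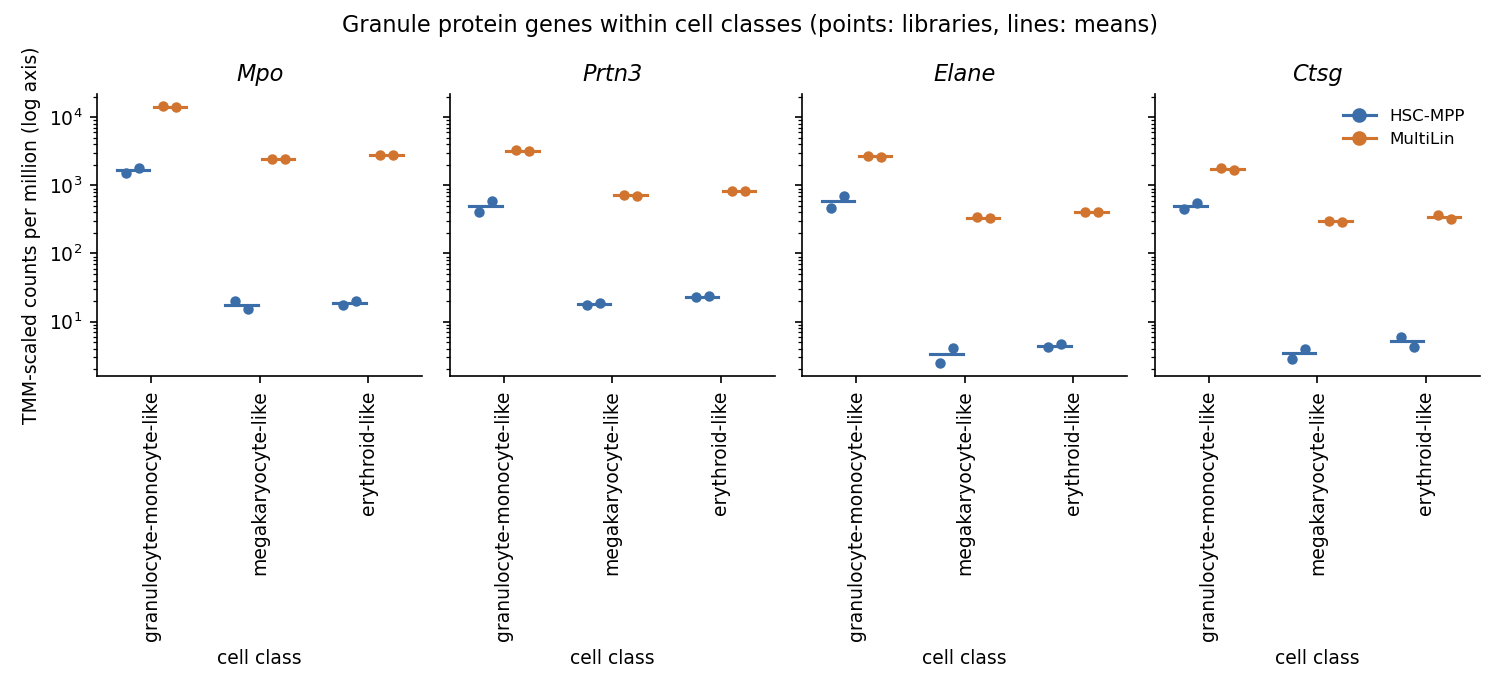
Mpo, Prtn3, Elane and Ctsg in TMM-scaled CPM (log axis) in granulocyte-monocyte-like, megakaryocyte-like and erythroid-like cells, with a point per library and a line at the mean of each population. In each class all MultiLin points lie above all HSC-MPP points, for Mpo with means of 14336 against 1676, 2463 against 17.6 and 2787 against 18.7.

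Single cells with UMIs of more than 1 lineage list were counted after each cell was thinned to 1000 UMIs. A UMI of any list gene counted, whether or not the gene is confined to 1 lineage. These included mitochondrial UMIs (medians of 14.4 and 14.7% of kept MultiLin and 5.12 and 5.49% of kept HSC-MPP cells). They also included ribosomal RNA repeats (24.8 and 21.3% against 1.71 and 1.64%). Thinned MultiLin cells thus held fewer UMIs of other genes, and depth in those genes was not equal. In MultiLin, 61.5 ± 0.125% of cells held at least 1 UMI of the granulocyte-monocyte list and 1 of the erythroid or megakaryocyte lists (mean ± SD, n = 2 libraries), against 16.8 ± 0.390% in HSC-MPP. Observed over the product of the single shares was 0.926 in HSC-MPP. In MultiLin it was 0.996, which says nothing on co-expression, since nearly all cells held a granulocyte-monocyte UMI and the ratio is then held near 1. In HSC-MPP, 61.3 ± 0.103% of cells held a lymphoid-primed UMI with an erythroid or megakaryocyte UMI, against 25.6 ± 1.51% in MultiLin (observed over product 0.994 and 1.03). The products were 61.7 and 24.8%. Independent detection of the 2 kinds of list would give shares close to these, so the overlap is no sign of co-expression. A granulocyte-monocyte UMI was found in 98.0 and 98.3% of MultiLin cells and in 23.1 and 23.8% of HSC-MPP cells. Erythroid-like cells, the class set beside these shares as a measure of background, held one in 96.2 and 97.3% of MultiLin cells (median 1644 and 2059 UMIs before thinning) and in 6.44 and 10.0% of HSC-MPP cells (6372 and 5987 UMIs). Expression of these genes by the erythroid-like cells was not excluded, so the MultiLin share was not divided into background and expression. With at least 2 UMIs of each list, 28.2 and 1.79% of MultiLin and HSC-MPP cells held granulocyte-monocyte with erythroid or megakaryocyte transcripts. Without thinning the shares were 81.6 and 64.2%, at unequal depth. No test was run on these shares.

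Antibody tags on the same cells differed between the populations, in part against the gates. Of 112 tags, 46 were higher and 45 lower in MultiLin, 12 and 19 of them by more than 2-fold. Sca1, the antigen that defines the HSC-MPP gate, fell most: its tag (Ly_6A_E_Sca_1) went from 9747 ± 31.6 to 682 ± 24.1 CPM (log2 -3.84, SE 0.04, adjusted p = 7.4e-06). CD86, a costimulatory ligand (-3.30), CD135, the Flt3 receptor (-2.96), and CD201_EPCR, a marker of stem cells (1799.7 to 299.8 CPM), fell next, followed by CD205_DEC_205 (-1.98), I_A_I_E (MHC class II, 2390 to 621), CD200_OX2 (-1.83), CD357_GITR (-1.63), PIR_A_B (-1.60) and CD270_HVEM. Up to 37.5% of the I_A_I_E counts of a library lay in 10 cells. Ly_6C rose most (2.61, 619 to 3773 CPM), followed by CD170_Siglec_F (an eosinophil lectin, 735 to 4381), anti_human_mouse_integrin_7 (239.8 to 1354), CD71 (the transferrin receptor, 2.42, 2523 to 13475), IL_33R__IL1RL1_ST2 (1.92), CD36 (1.88), CD62L (286 to 1011), anti_mouse_human_CD11b (1.70) and CD49d (1.41). The MultiLin gate excluded Ly6C and CD11b. Within erythroid-like and megakaryocyte-like cells, Ly_6C rose by 2.65 and 2.54, CD62L by 1.83 and 1.90 and CD36 by 1.79 and 1.76. CD170_Siglec_F rose there by 0.27 and 1.42, and stood at 5357 CPM in HSC-MPP erythroid-like cells. CD71 changed by -0.41 and 1.24. Some rises thus depended on the class and others did not, and tag background was not tested as a source. These tags were picked after their values were seen. Tags of the other gate antigens moved less: CD150_SLAM fell by 1.42, CD16_32 by 0.54 and CD117_c_kit by 0.47, and CD48 rose by 1.18. The balance of the calls depended on the scaling. With total antibody counts 68 rose and 31 fell (24 and 8 by more than 2-fold), and with isotype controls 30 rose and 48 fell (8 and 20). The median over all tags was 0.53 and -0.19 with these, against 0.03 with TMM. CD117_c_kit (0.03) and CD16_32 (-0.04) no longer passed with total counts. Of the 83 tags called both with TMM and with total counts, 6 had the opposite direction, none of them among the 20 with the largest changes.

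**Figure D4:**
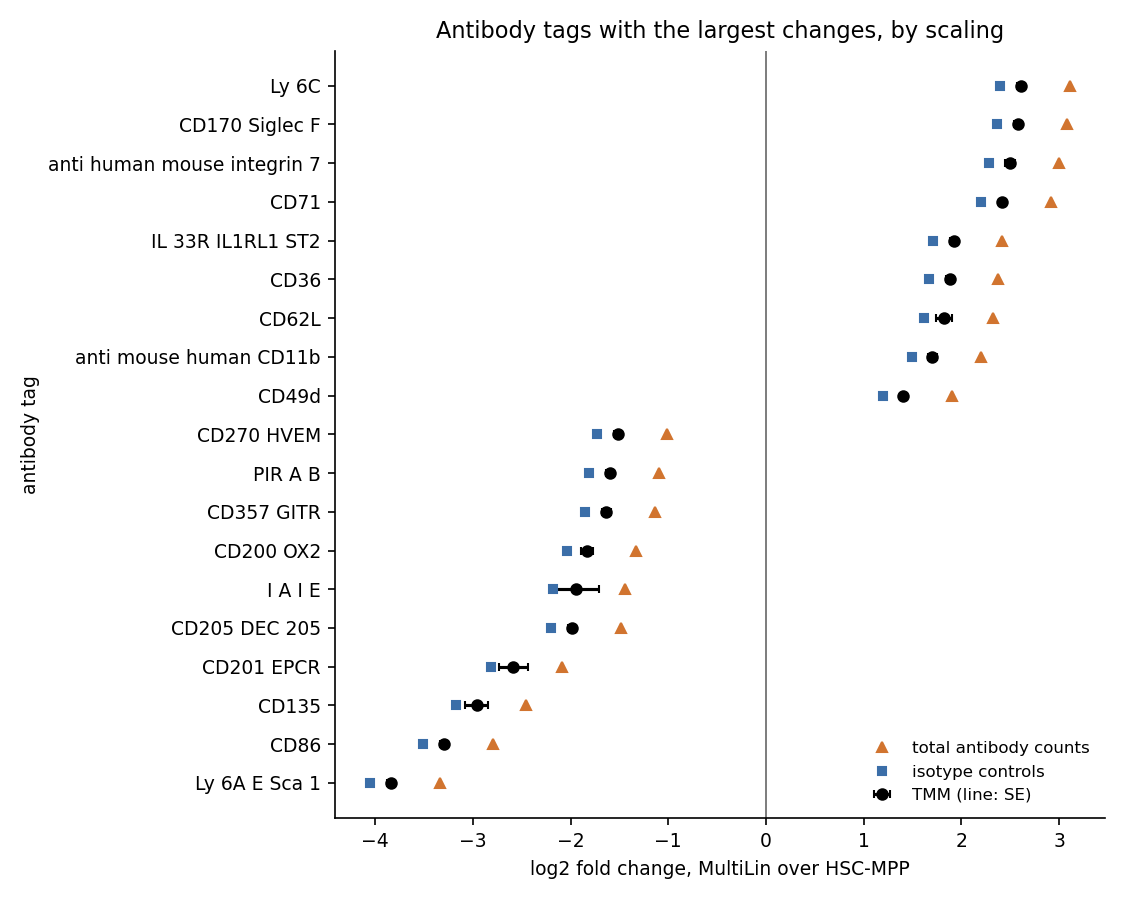
Log2 fold change, MultiLin over HSC-MPP, of 19 of the 20 tags with the largest changes, with circles for TMM scaling (lines are SE), triangles for scaling to total antibody counts and squares for scaling to isotype controls. The tags that fell lie below 0 and those that rose above 0 under each scaling, with Ly_6A_E_Sca_1 at -3.84 and Ly_6C at 2.61 under TMM.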

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

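The tests of free RNA with the make-up of the kept cells, of doublets, of cell class and of mitochondrial share as a source of the ribosomal RNA repeats were chosen only after the results were seen, and those of free RNA and of cell class took their present form, with both control sets required and with clusters in separate parts, after their values were seen. Barcodes over the mitochondrial limit entered only the setting with no such limit and, as a reference level, the test of free RNA below, and in MultiLin they held the granule gene Mpo at 7447 and 8015 CPM without TMM (replicates 1 and 2, 11156 and 10384 barcodes), against 4175 and 4639 CPM in kept cells, which is a signal in data left out of the main comparisons. Elane stood at 1335 and 1423 CPM in those barcodes against 589 and 652 in kept cells, and the stem cell gene Mecom at 65.9 and 58.2 CPM against 209 and 225. With 2 libraries a population, no test for a library far from the others was run.

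Granulocyte-monocyte transcripts were found in at least 94.6% of MultiLin megakaryocyte-like and erythroid-like cells in another random draw of 1000 UMIs. The called doublet share of barcodes was at most 17.9%, and these doublets had been removed beforehand. Cells with such a UMI held at most 0.904 of the median UMIs of the others. These values argue against doublets with granulocyte-monocyte cells as the source in most of these cells. Nearly all kept MultiLin cells held such a UMI, so its presence cannot mark doublets, and a part played by doublets in some cells was not excluded. Set against their level in the barcodes over the mitochondrial limit, granulocyte-monocyte genes reached at most 0.539 of what basophil genes reached, against an upper bound of 1.5 set before that value was seen. They reached 0.339 to 0.533 of what neutrophil genes reached. The bound has no lower limit, whereas free RNA of that make-up alone would give equal fractions. The test therefore leaves free RNA with the make-up of the left-out barcodes open as a source. Set against the level in kept cells, these genes reached 4.49 to 7.80 times the neutrophil genes and 2.77 to 3.21 times the basophil genes, and the lowest of these values lies between the bounds of 1.5 and 3, which leaves free RNA of that make-up open. Each control set holds 4 genes, and the MultiLin gate excluded CD11b and Ly6C, yet 110 and 129 kept MultiLin cells were mature neutrophil-like. Expression of these genes by the cells themselves, a biological difference between the gates, was not tested and stays open.

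The higher share of ribosomal RNA repeats in MultiLin was not accounted for by mitochondrial share, since among kept cells with 10 to 20% mitochondrial UMIs the lowest MultiLin median was 6.12 times the highest of HSC-MPP (20.2 to 22.8% against 3.08 to 3.29%). In the basophil, mast cell and eosinophil-like and the mature neutrophil-like clusters that held at least 10 kept cells of every library the ratios were 5.94 and 10.7 (20.6 to 26.6% against 2.10 to 3.46%, from 10 to 27 HSC-MPP cells a library), over the bound of 3. In a granulocyte-monocyte-like and an unnamed cluster they were 2.90 and 1.59, between the bounds of 1.5 and 3. The clusters were put in these parts after the ratios were seen, so the first part lay over 3 by that choice. Over all these clusters the lowest ratio was 1.59, and a part played by cell class stays open. In each of them the MultiLin median was still the higher. Library preparation and sorting went with the populations and cannot be told apart from them, and a biological difference was not tested.

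The opposite shifts of the HSC and granulocyte-monocyte lists were 6.43 ± 0.889 apart on the log2 scale, and 6.37 ± 0.886 apart after the trend with gene span was removed, which argues against gene length as their source. In this paragraph ± is an approximate SE of the difference of medians, with genes taken as independent, and not a spread between libraries. Among cells with 10 to 20% mitochondrial UMIs the lists were 2.01 ± 0.467 apart, between the bounds of 1 and 3, so that a difference in mitochondrial share may account for part of the distance. That window held only 399 and 415 HSC-MPP cells, more of them granulocyte-monocyte-like (14.8 and 18.3%, against 4.78 and 4.92% of all kept cells) and fewer HSC-like (0.752 and 0.964%, against 10.7 and 9.88%), which keeps the test from deciding. A difference between the gates, which the design names, was not tested against these and stays open.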

How the results depend on the processing

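The settings chosen only after the results were seen were no mitochondrial limit, cells with 10 to 20% mitochondrial UMIs, removal of mitochondrial and ribosomal RNA repeat features, the test against 2-fold, the shared cluster alone, naming against all 4 libraries, isotype scaling, cells not thinned, and leaving out libraries for shares of cells. Where values moved, the cause was not tested unless given. Of the 541 values of 32 named genes in whole libraries, 530 kept their direction and side of the threshold, as did all 238 values of 30 genes within classes, all 160 of 20 tags and 319 of 369 values of gene lists (28 lost the call, 16 gained one and 6 changed sign). Of the 16 gained list calls, 7 came with fry and 2 with cells thinned to 1000 UMIs. With replicate number as a block, 11556 genes passed in whole libraries, 6671, 5007 and 4244 within granulocyte-monocyte-like, megakaryocyte-like and erythroid-like cells, 94 tags and 20 lists, and no call changed among the 32 genes in whole libraries, 30 within classes, 20 tags and 31 lists to which it was applied. The labels give no pairing, and deviations of libraries with the same number had a correlation of -0.0150 over 14159 genes.

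In whole libraries (11744 genes), other settings gave 9657 to 13358 genes, except for 4521 with 10 to 20% mitochondrial UMIs and 3536 against 2-fold, a stricter question by construction. At most 5% mitochondrial UMIs moved the median of all genes from -0.05 to -0.20, gave 361 of 8799 shared calls the opposite direction and put Cd34 at -0.20 and Kit at -0.79 (94.8 and 90.3% of its MultiLin cells lay in 1 unnamed cluster), and Slamf1 stood at 0.087 with 10 to 20%. With at most 5%, 1 further named gene kept its direction but lost its call. Within granulocyte-monocyte-like cells (6817), DESeq2 gave 4409, thinning to 1000 UMIs 3063, resolution 0.5 1492 and the shared cluster 1661. Within megakaryocyte-like cells (5211), DESeq2 gave 3381, thinning 2709 and leaving out a library 2685 to 4651. Within erythroid-like cells (4227) the counts were 1824, 1355 and 2814 to 3574, and at resolution 0.5 no count was possible, as no MultiLin cells were in the class. Thinning lowers depth by construction.

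Of 20 lists that passed, 0 did with an estimated correlation and 13 did with 10 to 20% mitochondrial UMIs, 12 in the same direction and G2/M genes in the opposite one, where medians were 0.19 for monocyte-dendritic, -0.46 for erythroid, -0.49 for G2/M, 0.21 for immediate early and -0.12 for oxidative phosphorylation genes. For stroma and endothelium genes (median -0.56), fry passed (adjusted p = 0.00867) in the direction opposite to that of camera. Fry also passed 7 further lists that camera did not. These were lymphoid-primed (adjusted p = 0.00200 with fry), megakaryocyte (0.00445), B cell (0.0161) and T and NK cell genes (0.00592). The others were gate markers (0.00242), cell cycle inhibitors and quiescence (0.00200) and cytokine receptors (0.00510).

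Shares of cells were differences in points, MultiLin minus HSC-MPP. For HSC-like cells (-10.3) they were -9.22 with doublets kept, -8.20 with at least 1000 genes, -14.3 with no mitochondrial limit, 0.0680 at resolution 1.5 and -11.6 with cells thinned, but the MultiLin share itself rose to 13.7% with no limit and 10.6% at resolution 1.5. For lymphoid-primed-like cells (-15.8) they were -14.2 with doublets, 0 with at least 1000 genes, -30.2 with no limit, and -36.6 and -10.8 at resolutions 0.5 and 1.5. For granulocyte-monocyte-like cells (3.56) they were -0.623 with doublets, 18.8 with at least 1000 genes, 16.5 with no limit, 7.42 and 7.89 at resolutions 0.5 and 1.5, 11.1 thinned and 56.4 named against all 4 libraries. For megakaryocyte-like cells (-3.53) they were -5.66 with doublets, 18.2 with at least 1000 genes, -0.588 with no limit and 15.6 at resolution 0.5. For erythroid-like cells (18.9) they were -1.31 with at least 1000 genes, 7.32 with no limit, -2.11 at resolution 0.5, 24.3 thinned and -2.79 named against all 4 libraries. Basophil, mast cell and eosinophil-like cells (8.98) stood at 10.4 with at least 1000 genes and 7.34 with no limit. Mature neutrophil-like cells (1.66) stood at 0.785 with at least 1000 genes, 0.498 with no limit, 1.20 at resolutions 0.5 and 1.5 and 1.15 thinned. Macrophage-like cells (-1.63) stood at -1.12 with at least 1000 genes and at 0 with no limit, at resolution 0.5 and thinned. Monocyte-dendritic-like cells were absent from the main setting. Their mean share of MultiLin cells was 9.39% with no limit (HSC-MPP 0.149%) and at most 0.527% in the other settings.

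Cells with granulocyte-monocyte and erythroid or megakaryocyte UMIs differed by 44.7 points, and by 44.2 with doublets kept, 26.4 with at least 2 UMIs, 32.9 with no mitochondrial limit, 42.6 at 2000 UMIs and 17.3 with cells not thinned, where depth differed between the populations. Observed over product in HSC-MPP (0.926) was 0.946 with doublets, 0.696 with at least 2 UMIs, 0.976 at 2000 UMIs and 1.00 not thinned, and in MultiLin (0.996, held near 1 by saturation) 0.963 with at least 2 UMIs, 0.989 with no limit and 1.00 at 2000 UMIs and not thinned. Cells with lymphoid-primed and erythroid or megakaryocyte UMIs differed by -35.7 points, and by -21.2 with at least 2 UMIs, -42.6 with no limit and -46.7 not thinned. Their ratio was 0.959 with at least 2 UMIs and 1.00 at 2000 UMIs and not thinned in HSC-MPP (0.994), and 1.248 with at least 2 UMIs, 1.08 with no limit and 1.02 not thinned in MultiLin (1.03).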

Other observations

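The descriptions of clusters and the comparisons of tags with genes and of changes with gene span were chosen only after the results were seen. Clusters that met no class held cells with recognisable transcripts. A cluster of 263 and 260 HSC-MPP cells had Mx1, Rsad2 and Ifit1, genes induced by interferon, among the 10 genes with the highest fold over other HSC-MPP cells, and held 0 and 1 MultiLin cells. A cluster of 1235 and 1173 HSC-MPP cells, with a median of 8403 and 8171 UMIs, had the cell division genes Ect2, Cep55 and Kif23 among its top 10 and no MultiLin cell. The largest unnamed MultiLin cluster held 1895 and 2217 MultiLin and 60 and 41 HSC-MPP cells, and had Hlf, Mecom and Flt3 among its top 10 over other MultiLin cells. Another unnamed cluster, of 1451 and 1053 MultiLin cells and 0 and 1 HSC-MPP cells, had a median mitochondrial share of 0.813 and 0.728% and ribosomal RNA repeats at 44.6 and 40.7% of UMIs, with the ribosomal protein genes Rpl39, Rpl32 and Rps12 among its top 10.

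Tags and the genes of their antigens were compared for 83 tags with a tested gene. Of 60 pairs in which both were called, 45 moved in the same direction and 15 in opposite directions, with Pearson r = 0.594 and Spearman rho = 0.571 across pairs, which are not independent replicates. In all 15 the tag was lower and the gene higher. These tallies were made with TMM scaling only, and total antibody counts moved the median of all tags from 0.03 to 0.53. With the gene at 10 CPM or more, 36 of 48 called pairs had the same direction, with r = 0.700 and rho = 0.674 over 53 pairs. Ly_6A_E_Sca_1 and Ly6a (-3.84 and -3.72), CD86 and Cd86 (-3.30 and -3.53), CD135 and Flt3 (-2.96 and -2.74) and CD71 and Tfrc (2.42 and 2.28) moved alike. CD16_32 (-0.54) and Fcgr3 (4.99), CD43 (-0.63) and Spn (2.15), CD172a_SIRP (-1.14) and Sirpa (1.37), CD107a_LAMP_1 (-0.70) and Lamp1 (1.67), and CD117_c_kit (-0.47) and Kit (0.46) moved apart with TMM scaling. With total antibody counts, CD16_32 stood at -0.04 and CD117_c_kit at 0.03, so directions of small tag changes depended on the scaling. The pairs named here were chosen after their values were seen.

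Log2 changes varied with the genomic span of genes. In 4 equal groups of protein-coding genes from short to long (median spans 5708, 17018, 37685 and 113929 bp), the median log2 change was 0.46, 0.14, -0.03 and -0.26, and 21.8, 30.8, 39.5 and 52.0% of genes were lower in MultiLin. Spearman's rho with span was -0.259 across protein-coding genes and -0.147 across all 15268 genes with coordinates, and with exonic length 0.0213. These are correlations across genes, which are not independent replicates.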
